A study of Bacillus subtilis with 4 samples.

How the data were processed

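The 4 arrays each compared RNA of Bacillus subtilis NZ8900 overexpressing ykrK with RNA of the strain holding the empty vector. Cultures of 50 ml were started at an OD600 of 0.05, 13 OD units were collected and 16 µg of total RNA was labelled, per the labels' protocols. The labels state 3 cultures per strain, with 1 culture sampled in double volume for a technical replicate, without saying which 2 arrays share it. The 4 arrays were therefore treated as 4 replicates, and each of the 6 possible pairs was averaged in turn as an alternative. Where 2 arrays share a culture, part of the spread behind the p-values is technical.

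The authors deposited 1 table per array with raw, background and net intensity for both channels, as trimmed means per the file headers. The scanner and image software are not given in the sources used here. Net intensity equalled raw minus background, with negative values set to 0, in a check of every spot. Channel identity came from the labels, which tie channel A to Cy3 and channel B to Cy5. The authors also deposited a table of 1 linear ratio per gene and array, for 4106 genes, whose normalization is not given in the sources used here. Its log2 values correlated with log2 Cy5 over Cy3 at 0.48 and 0.56 on the arrays with ykrK in Cy5 and at -0.63 and -0.64 on the others, so it runs as ykrK over control. Its column medians were 1.03, 0.995, 1.02 and 0.992, and how it was centred stays unknown. It lacks 320, 236, 468 and 174 values on replicates 1 to 4. After dropping 14 summary rows per array file, 11664 spots remained in 36 grids, of which 3330 were empty and the rest held 4106 gene probes and 61 control probes, 2 spots each. Spot flags, slide numbers and scan dates are not in the tables, so alternatives with flags or slide as a block were not run.

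Background was corrected with normexp and an offset of 50, which shrinks ratios of dim spots towards 0. A single loess curve was fitted to the gene spots of each array in limma 3.58.1 under R 4.3.3, with control and empty spots at weight 0. Arrays were not normalized against each other. Ratios were turned to ykrK overexpression over control and the 2 spots of a gene averaged. The limma functions lmFit and eBayes tested each mean ratio against 0, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No dye term was fitted, since the swapped dyes are balanced and a dye effect cancels in the mean. It does not cancel in the spread, so SDs and p-values of this fit include dye differences. With a dye term 591 genes had an unadjusted p under 0.05 in limma, against 299 without. Gene symbols are those of the array tables. Of the 4106 gene probes 4038 matched a locus tag of the RefSeq annotation of assembly ASM904v1, which was used for newer names and for gene order only. No genome build is given in the sources used here, so coordinates are not printed.

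The design, including the single curve per array, the 26 gene lists and a set of other settings were fixed before the data were examined, and the single curve was kept although it gave 0 calls. The alternative per grid used a loess span of 0.3. The lists were tested with camera at a preset correlation of 0.01, with ykrK left out of every list, lists of at least 3 genes, and adjustment over the lists. They cover the ykrK locus, Rok-repressed genes, membrane protein quality control, class I and class III heat shock, SigB, SigW, the lantibiotic and bacitracin response, competence, motility and chemotaxis, biofilm matrix, early sporulation, potassium transport, methionine salvage, iron uptake, TCA cycle, glycolysis, purine, pyrimidine, arginine, branched-chain amino acid, and tryptophan and histidine biosynthesis, ATP synthase, PBSX, SPbeta and ribosomal proteins. The Rok list had 22 entries but 21 genes, because a synonym of sunS had also been entered for bdbA, which is therefore missing from it. The SPbeta list took genes by the start of their symbol and so includes bdbC and bdbD, which lie outside the prophage. Members of each list were also adjusted over that list alone, with no adjustment across the 26 lists. A gene therefore passes more easily in a short list.

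Named genes followed a rule fixed at the same time. It took all genes of the ykrK locus list and rok, then up to 12 genes in each direction past the threshold with the same sign on all arrays, then, with fewer than 20 past it, those of lowest unadjusted p with the same sign on all arrays until 20 were named. It also took the 4 members of each list with the largest absolute ratio. Other genes were named after their values were seen, namely sspD and ykzE, members of a list that passed over that list alone, and genes called with a curve per grid. A gene counted as detected on an array when its net intensity exceeded the 95th percentile of the empty spots. By that rule 92.3, 93.7, 93.4 and 98.1 percent of genes were detected in Cy3 and 86.1, 90.6, 86.7 and 93.6 percent in Cy5 on replicates 1 to 4. Log ratios of the duplicate spots correlated at 0.87 to 0.95 within arrays.

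The fit was tested on simulated data for this comparison, with the real dye coefficients and residual spread and 200 of 4106 genes changed. At log2 changes of 0.5, 1, 2 and 4 it recovered 42, 82, 96 and 98 percent of 50 genes each, with 2 false calls. With dye coefficients and spread from values with a curve per grid it recovered 88, 96, 100 and 100 percent, with 4 false calls. No curve was fitted to simulated values, so neither the curves nor the false calls they may add were tested. In the real data ykrK at 5.76 did not pass with the single curve, so these shares need not hold there. In a further simulation of 4106 genes camera called the 1 list shifted by 0.5 and no other. Noise beyond the dye coefficients was drawn independently for each gene there. False list calls from other correlation between genes were therefore not tested. Alternatives varied background, normalization, dim genes, a dye term, spot averaging, variance model, array weights, replicates and thresholds, and used the authors' ratios.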

Results

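Gene expression was measured in Bacillus subtilis with 4 two-colour spotted arrays. Each array set RNA of a strain that carried ykrK on a plasmid against RNA of the same strain with the empty vector. Subtilin, a peptide antibiotic used here as the inducer, had been added to both at 0.1% when the cultures reached an OD600 of 0.8, and cells were taken 30 min later at 37 °C. The labels name the vector pNZ8902 in the sample description and pNZ8900 in the titles, so its identity is not settled here. The ykrK RNA carried Cy5 on replicates 1 and 3 and Cy3 on replicates 2 and 4. Each array held 11664 spots, with 4106 gene probes spotted 2 times each. The median net intensity over gene spots lay between 33.3 and 58.4 in Cy3 and between 152.2 and 348.3 in Cy5, and 3220 genes were above the empty spots in both channels of all 4 arrays. The number of arrays limits the precision of every value below. All values are log2 ratios of the ykrK-overexpressing strain over the control, given as mean ± SD over the 4 arrays.

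The comparison asked which genes respond to excess YkrK, a regulator encoded next to ykrL (htpX), the gene of a membrane-bound metalloprotease. The ykrK transcript itself rose 54.1-fold (5.76 ± 0.83, n = 4 arrays from 3 cultures per strain) and was higher on 4 of 4 arrays. The offset in the background correction lowers this value, which was 7.09 from net intensity and 7.12 in the authors' deposited table. The neighbouring ykrL fell to 0.316 of its control level (-1.66 ± 0.28), and was lower on 4 of 4 arrays. Without the offset ykrL was at -2.13 from net intensity, and it was at -2.16 in the authors' deposited table. Among the 6 measured genes of the ykrK locus, adjusted over the list alone, ykrK and ykrL were the genes that passed. Their limma adjusted p was 0.000122 for ykrK and 0.000164 for ykrL. Purine biosynthesis genes ranked higher than other genes as a group in camera (adjusted p = 5.21e-07, and 0.724 with an estimated correlation), led by purC at 1.27 ± 1.03.

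Over all 4106 genes, 0 genes passed an adjusted p of 0.05 in limma, and 299 had an unadjusted p under 0.05. The adjusted p was 0.0652 for ykrK and 0.0747 for ykrL. These counts used a single loess curve per array. With a curve for each of the 36 grids of the slide, chosen as a second normalization ahead of the analysis, 60 genes passed, 37 higher and 23 lower. The 60 became 1, 0, 8 and 1 when replicates 1, 2, 3 and 4 were left out in turn. With the single curve followed by subtraction of each grid's median, a fit added after seeing the data, 4 genes passed. The other fits chosen ahead of the analysis, on all 4 arrays, called between 0 and 46 genes. In the fit per grid ykrK was at 5.74 ± 1.04 (adjusted p = 0.0279) and ykrL at -1.65 ± 0.15 (adjusted p = 0.00395). Averaging each possible pair of arrays that may share a culture moved the 60 to between 1 and 91. With arrays 1 and 2 or arrays 2 and 4 averaged ykrK did not pass per grid (adjusted p = 0.0697 and 0.157). There ykrL did (adjusted p = 0.0291 and 0.0448). With the single curve, arrays of opposite dye orientation correlated at a mean r of -0.20 across genes, and arrays of the same orientation at 0.69. With a curve per grid these means were 0.50 and 0.58 (genes are not independent replicates).

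**Figure D1:**
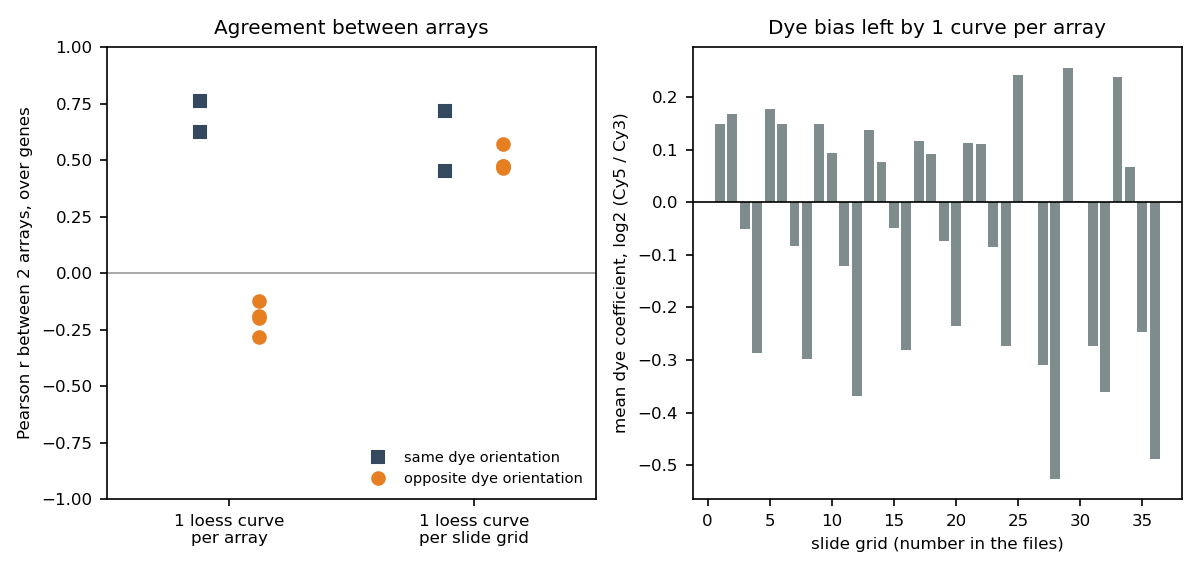
The left panel shows Pearson r across genes for each pair of the 4 arrays, of the same (squares) or opposite (circles) dye orientation, with a single loess curve per array or a curve per slide grid, and the right panel the mean dye coefficient of the genes in each of the 36 grids, log2 Cy5 over Cy3, with the single curve. Pairs of opposite orientation averaged -0.20 with the single curve and 0.50 with a curve per grid.

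The other genes of the locus list had ratios near 0. The anti-sigma factor gene ykrI was at 0.09 ± 0.28, the potassium transporter gene ykrM at 0.00 ± 0.06, ykrP at -0.02 ± 0.20 and the histidine kinase gene kinE at 0.16 ± 0.31, and none of them passed over the list alone. The value of kinE with a curve per grid, 0.17 ± 0.07, passed over the list alone (adjusted p = 0.0155) but not over all genes. Of the nearest neighbours outside the list, sspD was at 0.09 ± 0.06 and ykzE, whose 2 spots touch ykrK spots, at 0.48 ± 0.33. In the control RNA sspD was above the empty spots on 3 of 4 arrays and ykzE on 2. The gene ykoX, on the other side of sigI, was at -0.92 ± 0.16 (adjusted p = 0.105 over all genes, 0.0377 with a curve per grid). Without the offset sspD was at 0.97 and ykzE at 2.98 from net intensity, and in the authors' deposited table sspD at 1.33 passed (adjusted p = 0.0315) and ykzE at 2.78 did not (adjusted p = 0.105). Values without the offset put ykoX at -2.50 from net intensity and at -2.42 in the authors' deposited table, where it passed (adjusted p = 0.00933). The ykrK ratio rested on a control signal well below that of the ykrK strain. On replicate 1 the net intensity of ykrK was 27960 in Cy5 against 54.3 in Cy3, and on replicate 4 it was 5730 in Cy3 against 470.4 in Cy5. In the authors' deposited table the ykrK ratio ran from 96.5 to 205.5 and that of ykrL from 0.187 to 0.279.

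**Figure D2:**
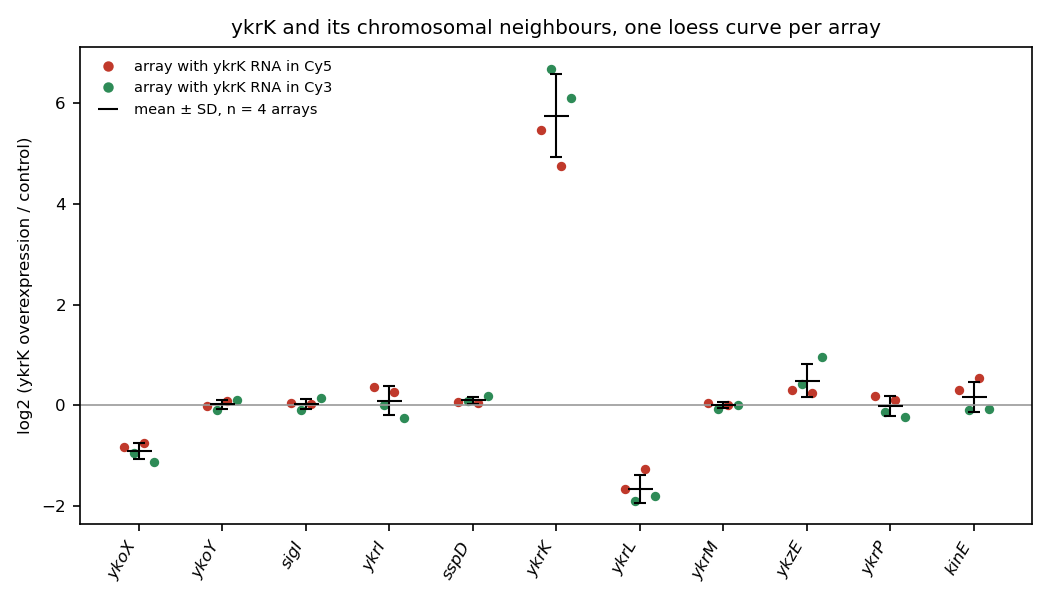
Log2 ratio of ykrK overexpression over control for ykrK and the 5 genes on each side, in chromosomal order; points are single arrays coloured by the dye of the ykrK RNA, bars are mean ± SD over 4 arrays. The ratio was 5.76 for ykrK and -1.66 for ykrL.

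The gene rok, which encodes a repressor of competence and of several peptide and prophage genes, was at -0.33 ± 0.16 and lower on 4 of 4 arrays (adjusted p = 0.460). It did not pass with a curve per grid either (-0.37 ± 0.23, adjusted p = 0.116). Of the 21 measured Rok-repressed genes, which include rok itself, 17 were below 0 and 6 were below 0 on all arrays, with a median of -0.24, and 0 passed over the list alone. The lowest were the peptide gene yydF at 0.499 of its control level, yybN at -0.68 ± 0.42, and yvaW and yvaX of the sdp toxin operon at -0.66 ± 0.48 and -0.52 ± 0.34. The list was lower than other genes in camera with a preset correlation of 0.01 (adjusted p = 4.66e-05), but not with an estimated correlation (adjusted p = 0.724). A curve per grid ended the camera call (adjusted p = 0.0763) and gave a median of -0.10, with yybN at -0.04 ± 0.02. In that fit yydF was at -0.49 ± 0.48 and yvaW at -0.66 ± 0.50. The yyb and yyd genes of the list lay in grids of 20 or 21 genes. A curve through so few spots may take up part of a gene's own ratio, which was not tested. From net intensity yybN was at -0.68, and in the authors' deposited table at -0.36.

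Camera called 7 of the 26 gene lists, all of them with the preset correlation. Besides the Rok-repressed genes they were purine biosynthesis, motility and chemotaxis, the SPbeta prophage, the SigB general stress genes, pyrimidine biosynthesis and the SigW genes, each shifted upwards. With an estimated correlation none of the 26 was called, and these 7 each had an adjusted p = 0.724. Fry called none either, with adjusted p from 0.576 to 0.894. A curve per grid also called 7 lists, with the TCA cycle in place of the Rok-repressed genes. These calls too were absent with an estimated correlation (adjusted p = 0.830 for each of the 7) and with fry (adjusted p from 0.108 to 0.325). List medians elsewhere in this text come from the single curve unless a fit is named. In the authors' deposited table the medians were 1.02 for purine, 0.42 for pyrimidine, 0.31 for SigB, 0.28 for SPbeta, 0.19 for SigW, 0.17 for motility and -0.24 for Rok-repressed genes, against 0.03 for all genes. After median centring those of SPbeta and SigB were 0.19 and 0.21. Some lists that were not called rose as well, with tryptophan and histidine at 0.21 and arginine at 0.16, against 0.05 for all genes.

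Purine biosynthesis gave the largest list median, 0.54 over 14 genes, and 13 of the 14 were above 0, with the camera result given above. The leading members were purC at 1.27 ± 1.03, purB at 1.06 ± 0.85, purS at 1.02 ± 0.84 and purE at 0.77 ± 0.79, of the operon for IMP synthesis. Over the list alone purA, for adenylosuccinate synthetase, was the 1 gene that passed (0.56 ± 0.22, adjusted p = 0.0425), although its ratio was 0.11 ± 0.08 with a curve per grid. On replicate 1, with ykrK in Cy5, purC was at 0.02 and purS at 0.14 with the single curve. In the fit per grid 4 purine genes rose over all genes tested, namely purC at 1.40 ± 0.46, purB at 1.18 ± 0.41, purS at 1.09 ± 0.33 and purK at 0.70 ± 0.24, and over the list alone 12 rose and 1 fell. The gene that fell per grid was guaB, for IMP dehydrogenase, at -0.42 ± 0.26. The GMP reductase gene guaC, which is not in the list, was at 1.22 ± 0.35 and did not pass (adjusted p = 0.245). Without the offset guaC was at 2.43 from net intensity and at 2.45 in the authors' deposited table, where it passed (adjusted p = 0.0103), as did purC at 1.97, purB at 1.80, purS at 1.85, purK at 1.41, purE at 1.47, purQ at 1.49, purL at 1.08 and purF at 0.95. Of the 10 pyrimidine genes 9 were above 0 (camera adjusted p = 0.00144, and 0.724 with an estimated correlation), with a median of 0.13. The largest ratios were those of pyrB at 0.54 ± 0.25, pyrAA at 0.43 ± 0.26 and the uracil permease gene pyrP at 0.34 ± 0.36. In the fit per grid pyrAA rose at 0.42 ± 0.11 (adjusted p = 0.0455), but not with a dye term added (adjusted p = 0.0622). Over the list alone 4 members rose per grid.

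**Figure D3:**
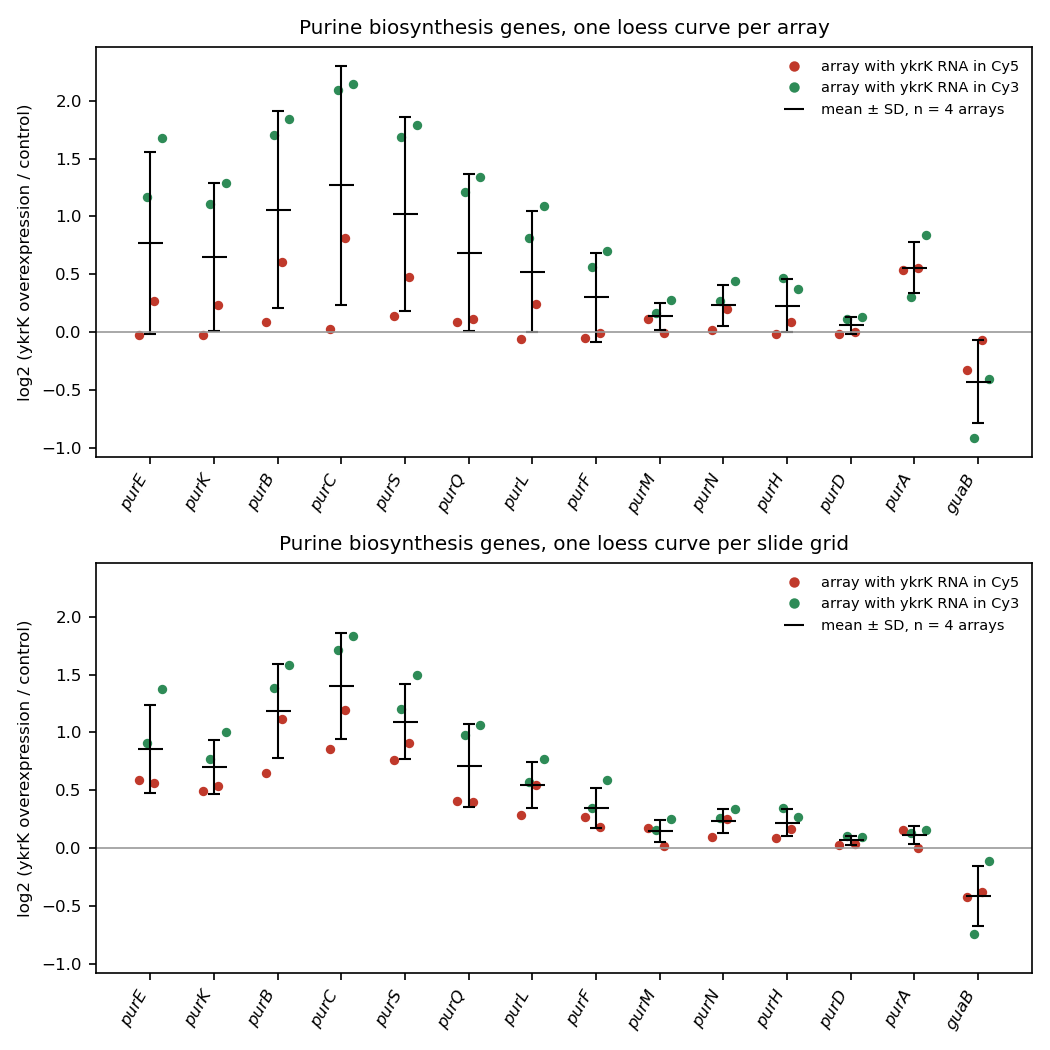
Log2 ratio of ykrK overexpression over control for the 14 purine biosynthesis genes, with a single loess curve per array (top) and a curve per slide grid (bottom); points are single arrays coloured by the dye of the ykrK RNA, bars are mean ± SD over 4 arrays. With a curve per grid 12 of the 14 genes were above 0 on all 4 arrays and guaB was below 0 on all 4.

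Motility and chemotaxis genes had a median of 0.14, and 39 of 47 were above 0 (camera adjusted p = 2.87e-06, and 0.724 with an estimated correlation), while 0 passed over the list alone. The largest ratios were those of lytE, for a cell wall hydrolase, at 0.48 ± 0.34, and of the flagellar genes fliI at 0.41 ± 0.21, fliG at 0.37 ± 0.23 and flgE at 0.33 ± 0.11. The hook-filament junction gene flgK passed over all genes with a curve per grid (0.34 ± 0.08). Of 29 SigB general stress genes 25 were above 0, with a median of 0.12 (camera adjusted p = 6.56e-05, and 0.724 with an estimated correlation). Among them gsiB was at 0.53 ± 0.52, csbA at 0.49 ± 0.52, ctc at 0.44 ± 0.95 and gspA at 0.43 ± 0.37. Without the offset gsiB was at 1.13 and csbA at 1.07 from net intensity, and in the authors' deposited table gsiB at 1.33 passed over all genes (adjusted p = 0.0248) and csbA at 1.19 did not (adjusted p = 0.0524). None passed over the list alone, and with a curve per grid 5 did, gsiB, csbA and ctc among them. Of 34 SigW genes 22 were above 0, with a median of 0.10 (camera adjusted p = 0.0207, and 0.724 with an estimated correlation). The flotillin gene yuaG was at 0.44 ± 0.36, the penicillin-binding protein gene pbpE at 0.43 ± 0.33 and ydjP at 0.38 ± 0.65. Per grid pbpE rose over all genes (0.44 ± 0.12, adjusted p = 0.0455), but not with a dye term added (adjusted p = 0.0653). Over the list alone 12 SigW genes rose per grid and yknX fell. The SigW list was not called without replicate 3 (adjusted p = 0.203) or without replicate 4 (adjusted p = 0.156). Of 166 genes taken as SPbeta, 128 were above 0 with a median of 0.05 (camera adjusted p = 8.04e-06, and 0.724 with an estimated correlation). The largest ratio was that of yonA at 0.57 ± 0.15, and yolA at -0.49 ± 0.42 and yolB at -0.46 ± 0.35 lay on the other side of 0.

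The remaining lists were not called by camera. The membrane protein quality control genes held ykrL, which passed over that list alone, and a mixed set besides, with the protease gene clpP at -0.59 ± 0.29, the foldase gene prsA at -0.50 ± 0.87 and yqfB at 0.46 ± 0.39 (20 genes, median -0.10, adjusted p = 0.535). The fit per grid had ykrL and clpP falling over the list alone, while yuaG, yuaF, yqeZ and yqfB rose. Class I heat shock genes of the HrcA regulon had a median of -0.04 over 9 genes (adjusted p = 0.763), with groES at -0.38 ± 0.53 and dnaK at -0.20 ± 0.94. Their median was 0.01 with a curve per grid. Class III genes of the CtsR regulon had a median of -0.12 over 8 genes (adjusted p = 0.150). There clpP fell over the list alone (adjusted p = 0.0481), while mcsB was at -0.36 ± 0.80 and clpC at -0.28 ± 0.62. With the single curve clpP did not pass over the larger membrane list or over all genes (adjusted p = 0.378 over all genes). The lantibiotic and bacitracin response genes, listed because of the inducer, were near 0 with a median of -0.02 over 11 genes (adjusted p = 0.706). Both strains received subtilin, so a response common to both cancels in these ratios and cannot be seen here. The transporter genes ytsC and ytsD were at -0.15 ± 0.89 and 0.14 ± 0.27.

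Genes of other states of a culture moved little as groups. In the competence list smf (dprA), whose product loads RecA on incoming DNA, rose at 0.86 ± 0.07 over the list alone (adjusted p = 0.00073) and with a curve per grid over all genes (0.85 ± 0.14, adjusted p = 0.0279). It also passed in the authors' deposited table, where smf was at 1.24 (adjusted p = 0.0329). The list as a whole had a median of 0.02 over 23 genes (adjusted p = 0.237), with comFC at 0.14 ± 0.16. In early sporulation the pair rapA and phrA, for a phosphatase of the phosphorelay and its inhibitory peptide, rose over the list alone at 0.72 ± 0.30 and 0.87 ± 0.17 (adjusted p = 0.0321 and 0.00398), and both passed over all genes with a curve per grid. The gene spo0F, whose protein product RapA dephosphorylates, was at -0.54 ± 0.88, and per grid it fell over the list alone (-0.43 ± 0.15, adjusted p = 0.00745). The list of 22 had a median of 0.02 (adjusted p = 0.955). Biofilm matrix genes had a median of -0.03 over 20 genes (adjusted p = 0.556), with tasA at -0.28 ± 0.81 and yveO at -0.17 ± 0.52. The 31 PBSX prophage genes had a median of -0.01 (adjusted p = 0.763), with xtmB lowest at -0.11 ± 0.11.

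Among the metabolic lists that were not called with the single curve, the iron uptake genes came closest to a call (27 genes, median -0.13, adjusted p = 0.0557). Their camera adjusted p was 0.126 with a curve per grid. The bacillibactin genes dhbA at -0.67 ± 0.18, dhbC at -0.53 ± 0.15, dhbE at -0.42 ± 0.16 and dhbB at -0.35 ± 0.16 fell over the list alone, and ywbM rose at 0.46 ± 0.21. The flavodoxin genes ykuN and ykuP were at -1.10 ± 1.03 and -0.76 ± 1.19. Per grid dhbA and dhbC fell over all genes (adjusted p = 0.0459 and 0.0470), but not with a dye term added (adjusted p = 0.0660 and 0.0652). Over the list alone 11 genes fell per grid, with ykuN at -0.77 ± 0.33, and 3 rose. The potassium transport genes had a median of -0.02 over 9 genes (adjusted p = 0.185), with yhaS at -0.42 ± 0.24 and yhaT at -0.27 ± 0.17. With a curve per grid yhaS fell over all genes (-0.36 ± 0.07), but not with a dye term added (adjusted p = 0.0573). Without the offset yhaS was at -0.81 and yhaT at -0.87 from net intensity, and in the authors' deposited table yhaS at -0.85 and yhaT at -0.82 did not pass (adjusted p = 0.0903 and 0.112). The methionine salvage genes near the locus had a median of -0.07 over 8 genes (adjusted p = 0.185), with ykrT at -0.28 ± 0.49. In glycolysis gapA rose over the list alone at 0.44 ± 0.11 (adjusted p = 0.0179), fbaA was at -0.99 ± 1.40 with replicate 1 at -2.89 and at -0.28 ± 0.30 with a curve per grid, and the 14 genes had a median of -0.08 (adjusted p = 0.946). The 13 TCA cycle genes had a median of 0.08 (adjusted p = 0.378), with sucC at -0.46 ± 1.09 and sdhA at 0.27 ± 1.35. Per grid sucC was at 0.01 ± 0.10 and sdhA at 0.45 ± 0.16, and the TCA list was called upwards (adjusted p = 0.00589, 0.830 with an estimated correlation).

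Arginine biosynthesis had a median of 0.02 over 9 genes (adjusted p = 0.556). Its argD probe was above the empty spots on 2 of 4 arrays in the ykrK RNA and 3 in the control RNA, and carB on 0 in either, so a change in these could have gone unseen. The branched-chain amino acid genes had a median of -0.04 over 10 genes (adjusted p = 0.675), with ilvD at 0.07 ± 0.04. Tryptophan and histidine genes had a median of 0.00 over 16 genes (adjusted p = 0.808), and trpE was above the empty spots on 2 of 4 arrays in the control RNA. All 9 ATP synthase genes were below 0, with a median of -0.04 (adjusted p = 0.147) and atpI lowest at -0.29 ± 0.32, but the median was 0.06 with a curve per grid. Ribosomal protein genes went both ways, with a median of -0.03 over 53 genes while the camera direction was upwards (adjusted p = 0.675). Over the list alone rplV at 0.37 ± 0.02 and rpsS at 0.41 ± 0.13 rose and rplA fell, at -0.59 ± 0.20. Per grid rpsQ and rpmC rose over all genes and rplA, rplK and rpsM fell. With a dye term added rpsQ and rpmC still passed (adjusted p = 0.0412 and 0.0385). The calls of rplA, rplK and rpsM ended there (adjusted p = 0.0593, 0.0660 and 0.0660).

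The genes with the lowest unadjusted p and a shared sign on all arrays, none of which passed over all genes, included several outside the lists. The D-alanine aminotransferase gene dat was at -0.83 ± 0.11 (adjusted p = 0.0808) and fell with a curve per grid (-0.86 ± 0.16, adjusted p = 0.0377). The polyketide synthase gene pksL was at 0.59 ± 0.09 and the acyl carrier protein gene acpK of the same cluster at 0.39 ± 0.06. The genes bkdAA and lpdV, for subunits of the branched-chain keto acid dehydrogenase, were at 0.73 ± 0.21 and 0.55 ± 0.14, and both rose with a curve per grid (adjusted p = 0.0450). The gene yxeC was at -0.50 ± 0.12.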

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

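The test of regional dye bias and those of purine dye orientation and the wider purine regulon were chosen after their results were seen, and the tests with shuffled grids and sign patterns before. Among the 113 named genes 3 had an array far from the other 3, and chance gives about 1 in 20 groups. The ratio of yqfB was 1.05 on replicate 3 and between 0.21 and 0.31 on the others. The ratio of cggR was 0.41 on replicate 3 against 0.18 to 0.21. The ratio of argD was 0.21 on replicate 4 against 0.00 to 0.03. None of the 61 control probes, which include rRNA sequences, passed adjustment (lowest adjusted p = 0.980). A test of the mean cannot show a dye bias when the dyes are swapped in balance. The 23S rRNA probes followed the dye orientation, with 23S-4 at -1.46, 1.45, -2.25 and 1.77 on replicates 1 to 4 (SD 2.03).

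The count of 0 genes with a single loess curve and 60 with a curve per grid was weighed against dye bias across the slide and against overfitting. Of the variance of the dye coefficient between genes, 49.1 percent lay between grids with the single curve. The grid means followed the grid number with a period of 4, averaging 0.15, 0.11, -0.09 and -0.30, which is consistent with a bias across the slide. Whether overfitting by 36 small curves adds to the 60 stays open, since curves in 20 sets of shuffled grids called at most 4 genes but left 47.3 percent of that variance between grids, and on values with grid medians subtracted, which gave 4 calls, shuffled curves gave a median of 3. Over the 8 sign patterns of the 4 arrays, which are too few for a share under 0.05, the real pattern gave 60 calls and the highest other 0 (1 pattern as large), while with the single curve all 8 gave 0 and the highest other was 0.

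Of the 8 sign patterns 4 gave at least the 7 lists called by camera with the single curve, and the highest other, 8 lists, came from the pattern that follows the dyes. The remaining patterns with as many gave 7 lists and followed neither the strain nor the dyes. The patterns are too few for a share under 0.05. The calls hold at the preset correlation only, and with an estimated correlation 0 lists were called.

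The purine genes were higher on the arrays with ykrK in Cy3 than in Cy5, averaging 0.67 and 0.35 over the 14 genes with a curve per grid. A bias confined to 1 dye orientation is argued against by 13 of the 14 genes lying above 0 in both orientations. Many of these genes share an operon, so their signs are not independent. The count of signs cannot exclude a dye contribution to the size of the ratios. A wider change of the purine regulon may be present but was uneven in size. With a curve per grid 6 of 8 measured regulon genes outside the list were above 0 on all 4 arrays. The largest were guaC at 1.27 ± 0.50 and nusB at 0.45 ± 0.10. The genes pbuG, ytiP, glyA and yqiB lay between 0.10 and 0.28, xpt at 0.10 ± 0.31 and pbuX at 0.02 ± 0.41. None of those passed over all genes per grid. The authors' deposited table put all 8 above 0, from xpt at 0.27 to guaC at 2.45. There ytiP was at 1.11, pbuG at 0.94, pbuX at 0.85, nusB at 0.64, yqiB at 0.60 and glyA at 0.40. These 8 and the bound of 6, which the value just meets, were set after the values had been seen, and of the 8 nusB passed over all genes per grid and guaC and pbuG in the authors' deposited table. Whether the shared direction follows from YkrK or from a difference in the cultures stays open.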

How the results depend on the processing

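Combinations with a curve per grid, the dye term without background correction, the authors' table with a dye term and the subtraction of grid medians were added after seeing the data. The directions of ykrK, ykrL and rok held in all 37 alternatives, ykrK between 5.39 and 7.13, ykrL between -2.18 and -1.59 and rok between -0.45 and -0.26. Their adjusted p ranged from 4.65e-07 to 0.775, 2.48e-05 to 1.00 and 0.0393 to 1.00. Except where a value's construction shows it, the cause of a changed call was not tested. Calls numbered 0 with a single curve, 1 from net intensity (ykrK 7.09 passed), 6 without background correction (ykrK 5.86, ykrL -1.65), 60 with a curve per grid (5.74, -1.65), 1 after median centring (5.78), 2 without the dimmest 25 percent of genes (5.76, -1.66, fewer genes tested), 1 with a dye term (5.76), 24 in the authors' table (7.12, -2.16), 46 with replicate spots kept apart (5.76, -1.66), 3 with trended robust variances (5.76, -1.66), 5 with array weights (6.09, -1.76) and 1 with arrays 2 and 3 averaged (5.77). The calls in the authors' table were 20 higher and 4 lower, and of the 24, 14 were among the 60. With a curve per grid calls numbered 56 with a dye term (5.74, -1.65; 38 of them among the 60), 259 without background correction (5.84, -1.65, and rok at -0.38 passed) and 15 from net intensity (7.13, -2.18). The dye term without background correction gave 91 (5.86, -1.65), the authors' table with a dye term 15 (7.12, -2.16), and subtracting grid medians after the single curve 4 (5.77, -1.65), all 4 among the 60.

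Leaving out single arrays kept 0 calls with the single curve (ykrK 5.45 to 6.09, ykrL -1.79 to -1.59, rok -0.39 to -0.28). With a curve per grid the 60 calls became 1 without replicate 1 (ykrL -1.60 passed), 0 without replicate 2, 8 without replicate 3 (6.16, -1.66) and 1 without replicate 4 (-1.72). With pairs averaged as 1 replicate they became 2 for arrays 1 and 2 (-1.62), 91 for 1 and 3 (6.01, -1.63), 31 for 1 and 4 (5.70, -1.66), 14 for 2 and 3 (5.77, -1.65), 1 for 2 and 4 (-1.67) and 10 for 3 and 4 (5.85, -1.69), so the count depends on which arrays share a culture. With a curve per grid a threshold of 0.01 left 1 call, and a 2-fold bound at 0.05 left 7. The single curve had 0 calls at 0.05, so stricter thresholds could only leave 0. Camera called 7 lists, 0 with an estimated correlation and 0 by fry, and 5 to 10 over the other settings. Purine biosynthesis and SigB were called in all 35 camera alternatives run at the preset correlation. Motility was lost after median centring (adjusted p = 0.0644), pyrimidine with array weights (0.115), after centring (0.0884) and per grid without replicate 4 (0.0767), SPbeta in 3 combinations per grid (highest 0.122), SigW in 8 settings (highest 0.203) and the Rok-repressed genes in 9 settings, all per grid (highest 0.316). The other 110 named genes gave 4054 comparisons, of which 3839 kept direction and call or moved within 1 SD, 193 passed newly and 22 changed sign without a call by over 1 SD. None of the 110 passed with the single curve, so keeping the call meant staying uncalled. A much smaller ratio of the same direction also counted as kept, so the 3839 do not measure how stable the sizes are. Alternatives with spot flags or slide blocks were not run, since the tables hold neither. Each ratio already pairs the strains on an array, so no further paired fit was run. Dim spots limit the size of ratios, as the offset and net values of ykrK show.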

Other observations

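The tests of ykzE and sspD spots and of the genes around ykrK were chosen after their values were seen, and the test of the other spots touching ykrK before. Several operons outside the fixed lists were picked after their values were seen. All 7 genes of the branched-chain keto acid degradation operon were above 0 on all 4 arrays, between 0.41 for buk and 0.73 for bkdAA, with a median of 0.61. In the fit per grid 5 of the 7 rose over all genes, ptb, buk, lpdV, bkdAA and bkdAB. With a dye term added buk did not pass (adjusted p = 0.0622). All 6 genes of nitrate respiration, narK, fnr and narGHJI, were above 0 on all 4 arrays with a median of 1.01. On replicate 3 narI and fnr were at 0.03 and 0.06. The gene narK rose with a curve per grid (1.06 ± 0.33, adjusted p = 0.0455) but not with a dye term added (adjusted p = 0.0622). In the authors' deposited table none of these nitrate or keto acid genes passed (lowest adjusted p = 0.0623 for narK and 0.0903 for bkdAA).

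Of the 5 genes of the melibiose and msm operon, 4 rose with a curve per grid, amyD at 1.05 ± 0.31, msmE at 1.00 ± 0.22, amyC at 0.95 ± 0.31 and msmR at 0.70 ± 0.19, while with the single curve 1 of the 5 was above 0 on all 4 arrays. In the authors' deposited table msmE at 1.43, amyC at 1.56 and amyD at 1.56 passed (adjusted p = 0.0281, 0.0374 and 0.0493). The mannitol genes mtlA and mtlD rose per grid too, at 0.62 ± 0.05 and 0.33 ± 0.09, and mtlA passed in the authors' deposited table (0.83, adjusted p = 0.0417). With a dye term added per grid mtlD did not pass (adjusted p = 0.0660). Of 16 pks polyketide genes 11 were above 0 on all arrays with the single curve, with a median of 0.27, and 0 passed with a curve per grid. Genes that fell with a curve per grid included the cytochrome bd gene cydA at -0.59 ± 0.19 and ydbN (fbpB) at -0.88 ± 0.23. With a dye term added cydA did not pass (adjusted p = 0.0660) and ydbN did (adjusted p = 0.0456).

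Near ykrK, ykzE and sspD had higher ratios, and ykoX a lower one, in values without an offset. From net intensity ykzE was at 2.98 and sspD at 0.97, against 0.48 and 0.09 with normexp, and in the authors' deposited table at 2.78 (adjusted p = 0.105) and 1.33 (adjusted p = 0.0315). Signal from the bright ykrK spots is a candidate source for ykzE, since 2 of its 2 spots touch a ykrK spot, but 0 of the sspD spots do, so it cannot account for sspD. The 7 other genes touching ykrK spots had a median at percentile 86.2 of random sets, which decides neither way, and the genes around ykrK stood at percentile 93.9 of all windows in absolute statistic, short of the 95 set as the bound. The sspD ratio stays unexplained.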
